A study of Homo sapiens with 67 samples.

How the data were processed

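The data are bulk RNA-seq of purified beta-like cells at day 24 of differentiation from the human embryonic stem cell line MEL1 with an insulin reporter, in 67 libraries. Of these, 61 came from knockouts of 20 genes and 6 from wild type. The authors deposited 1 table of raw read counts for 67130 genes. Per the submitters' processing notes the RNA was isolated with Absolutely RNA Nanoprep kits, the libraries were made with TruSeq kits, and reads were aligned with STAR (version given as 2.73a) to GRCh38. The counting program, its annotation and its strand setting are not given in the sources used here. All 37 mitochondrial genes have 0 counts in every library, so mitochondrial transcripts could not be analysed. INS-IGF2, which overlaps INS, has 0 counts as well, so how reads of the overlap were assigned is open.

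Library totals ran from 9191724 to 79955120 counts, with a median of 22127971. For each of 69 pairs of libraries of 1 group, the mean chi-square over genes with more than 50 counts in the pair was between 1.55 and 104.54, where sampling noise alone gives about 1, so no pair differed by sampling noise only. Reads carry no molecular identifiers, and the floors and Poisson intervals cover counting error only. A gene with 0 counts in a group was given a floor of 3 counts over the group, and a gene with 1 to 3 counts a ratio with its exact Poisson interval. Against wild type, bounds and ratios use the mean of all 6 wild-type libraries. They are smaller against the lower wild-type set where WT1 and WT2 differ, as for H19 (7.44 to 37.5 CPM over the wild-type libraries).

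Samples were grouped by the knocked-out gene in their labels, with WT1 and WT2 as 1 wild-type group, giving 21 groups. Genes with low counts were removed with edgeR's filterByExpr at its default settings, which left 21766. Counts were scaled by TMM, and edgeR 4.0.16 in R 4.3.3 fitted 1 quasi-likelihood model to all 21 groups. Each knockout was compared with the 6 wild-type libraries, ABCC8 with KCNJ11 and HNF1A with HNF4A. In a fit of 22 groups, with WT1 and WT2 apart, WT1 was compared with WT2 and each knockout with WT1 alone and with WT2 alone. P-values were adjusted by the Benjamini-Hochberg method in each comparison, with a threshold of 0.05. These p-values measure the spread between the libraries here. Whether the libraries of a group are clones, differentiations or repeats is not given in the sources used here, so whether that spread includes the one between lines with the same edit is open.

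Gene lists, 32 with 722 members, were fixed before the data were examined. Of these, 31 had tested members and were tested in the 20 knockouts with camera (limma 3.58.1), with a preset correlation between genes of 0.01 and again with an estimated one, and the 620 tests were adjusted together. Each list also has its members past the threshold over all genes and adjusted over the list alone. The similarity of knockouts is Pearson's r and the covariance of log2 fold changes across genes. As knockouts share their controls, it was set against simulated groups with no change and against splits of the controls.

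The genes named were chosen by a rule fixed before the data were examined. It took the target, and INS, GCG, SST, PDX1, NKX6-1 and MAFA, in every knockout. It then took genes with an adjusted p under 0.05, an absolute log2 fold change of at least 1, the same sign against WT1 and WT2, every knockout library on the same side of the wild-type mean, a mean log2 CPM of at least 1 and a gene name other than a clone identifier. Of these it allowed the 10 highest and 10 lowest in HNF1A, HNF4A and the 3 other knockouts with the most genes past the threshold (KCNJ11, GIPR and CDKAL1), 4 and 4 in the others and 5 and 5 in the direct comparisons of knockouts. It also allowed the 3 members with the smallest adjusted p of each called list. Fewer were printed than the rule allows.

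Alternatives planned before the data were examined were RLE size factors, DESeq2 1.42.0, no filter on low counts, WT1 alone or WT2 alone as the control, a fit of only the groups compared, the replicate number as a block, the estimated correlation in camera, and leaving out each library in turn. The replicate numbers were tested for pairing. In 36 pairs of groups with 3 or more shared numbers, 1 (CDC123 with WT1) had every pair of libraries with the same number correlated above 0.1, and of 4 with fewer 1 did (GIPR with WT1), so the numbers were not taken to pair the samples. Chosen after seeing the data were the removal of each library's trend on GC content and transcript length with spline offsets (GENCODE sequences gave GC values for 21381 genes, 98.2% of those tested), the count of genes past the threshold against WT1 and against WT2, and the comparison of each group's mean with the other 21 group means with limma.

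The methods were tested on simulated data with 100 genes raised or lowered 2-fold and 100 changed 4-fold. In the HNF1A design edgeR called 89 and 100 of them with 7 false calls among 21566 unchanged genes, DESeq2 on 9 samples called 92 and 100 with 31, and the group means test called 93 and 100 with 16. With the GC and length trends of the KCNJ11 libraries added, edgeR called 78 and 99 with 3197 false calls, and with the correction 89 and 100 with 12. Camera called a list shifted 2-fold and 0 of the 30 others. In the real data WT1 and WT2, which share a genotype, differed in 5002 genes. The simulated counts therefore check the methods against the simulated noise only. They do not measure false calls or power where groups of like genotype differ. Y-linked genes and XIST were left out of every table. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.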

Results

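RNA was sequenced in bulk from pancreatic beta-like cells, the insulin-producing cell type of the islet, grown from the human embryonic stem cell line MEL1 with a fluorescent reporter in its insulin gene. The cells were purified at day 24 of differentiation. The series holds 67 libraries, of which 61 came from cells with 1 of 20 genes associated with type 2 diabetes knocked out and 6 from wild-type cells. Each knockout had 3 libraries, except WFS1 with 4, and the wild-type libraries carried the names WT1 and WT2, with 3 libraries each. Library totals ran from 9191724 to 79955120 counts, with a median of 22127971. Each knockout was compared with the 6 wild-type libraries to ask how loss of the gene changed the transcriptome of the cells. After a gene name, the text gives the log2 fold change ± an approximate standard error and edgeR's adjusted p. This error was derived from edgeR's quasi-likelihood F test, as the absolute log2 fold change divided by the square root of F. The model pools the spread over all groups, so the error does not measure the spread within 1 knockout. Levels are in CPM, counts scaled to the library total times the edgeR TMM factor, as mean ± SD (n = 3 for a knockout, n = 4 for WFS1, n = 6 for wild type). Of 360 pairs of a gene and a knockout that were followed through the alternatives and passed the test against wild type, most of them named below, 358 had every knockout library on the called side of the wild-type mean. The exceptions were GCG in the HNF1A knockout and KCNJ11 in its own knockout, each with 2 of 3 libraries.

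The targeted genes were measured first, in every library, with whole-gene counts. APOE, which encodes a lipid-carrying apolipoprotein, was at 13.8 ± 2.0 CPM in its knockout against 460 ± 170 in wild type (-5.06 ± 0.35, adjusted p = 4.4e-17). TGFB1 fell from 62.4 ± 9.6 to 10 ± 0.54 CPM (-2.64 ± 0.19) and IGF2BP2 from 184 ± 21 to 44.8 ± 3.0 CPM (-2.04 ± 0.08). Smaller decreases passed the test for TCF7L2 (-0.81 ± 0.11), HTT (-0.78 ± 0.10), WFS1 (-0.78 ± 0.16), TLE4 (-0.68 ± 0.10), KCNJ11 (-0.59 ± 0.17) and HNF4A (-0.45 ± 0.10), with adjusted p of 0.0036 or lower. COBLL1 rose (1.31 ± 0.13, adjusted p = 8.6e-12) and so did HNF1A (0.86 ± 0.20, adjusted p = 0.00028). ABCC8, CDC123, CDKAL1, GCKR, GIPR, SLC30A8, SLC16A11, TMCC2 and WDR13 did not pass, with log2 fold changes from -0.43 ± 0.16 for TMCC2 to 0.31 ± 0.25 for SLC16A11. Which part of each gene was edited is not given in the sources used here, and a count over a whole gene does not show a frameshift or a small deletion, so the genes that did not fall do not check their labels.

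**Figure D1:**
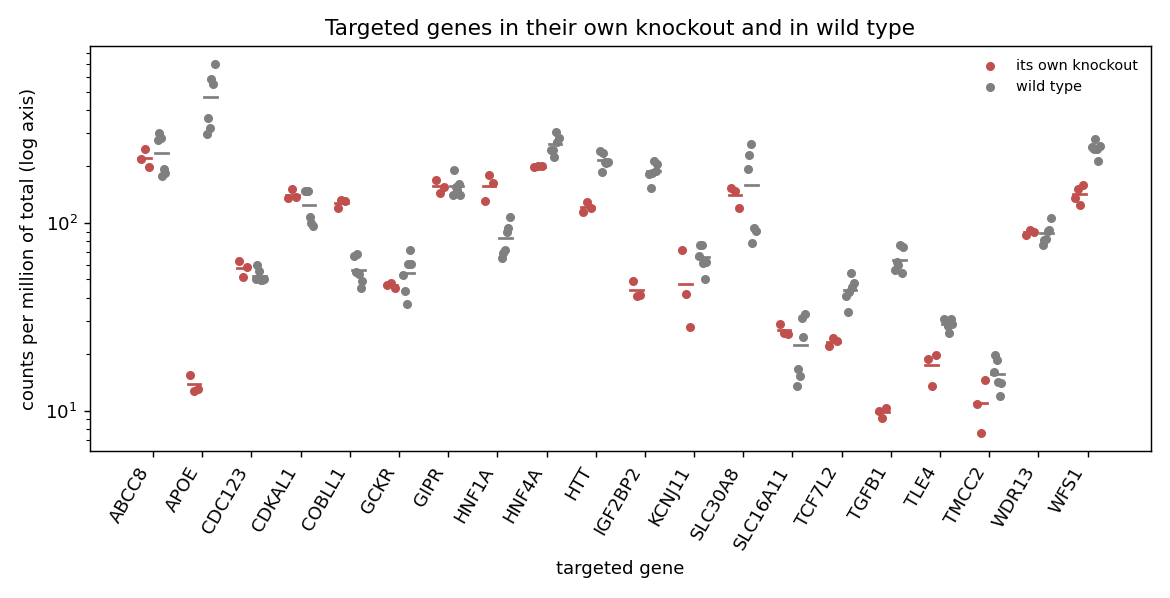
CPM of the library total (log axis) of each targeted gene in the libraries of its own knockout (red) and in the 6 wild-type libraries (grey), 1 point per library, with a line at each mean. APOE, TGFB1 and IGF2BP2 lie far below wild type, while COBLL1 and HNF1A lie above it.

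The number of genes past an adjusted p of 0.05, among 21766 tested, ran from 165 in the SLC30A8 knockout to 9697 in the HNF4A knockout. The wild-type sets also differed from each other. WT1 against WT2 gave 5002 such genes, 2797 higher and 2205 lower in WT1, of which 1432 changed at least 2-fold; without WT1 replicate 3 the count was 3143. FOSB, an immediate early gene, was at 314 ± 30 CPM in WT1 and 20.6 ± 3.5 in WT2 (n = 3 each; 3.93 ± 0.51, adjusted p = 1.2e-07), and ID3, a BMP target, was higher as well (3.18 ± 0.39). TF, which encodes transferrin, was lower in WT1 (-4.07 ± 0.26), as were MAGEH1 (-3.54 ± 0.34), FRG1BP (-3.45 ± 0.22) and NNAT (-2.84 ± 0.32). Among the endocrine genes INS (-0.93 ± 0.28, adjusted p = 0.014), SST (-0.77 ± 0.18) and PDX1 (-0.92 ± 0.16) were lower in WT1, and GCG did not pass (0.08 ± 0.25). Immediate early genes rose in 10 of 25 members and cholesterol synthesis genes fell in 11 of 24, with camera adjusted p of 0.00014 and 0.00038. Camera also called enterochromaffin-like cell (0.00038), heat shock (0.00083) and TGF-beta and BMP target genes (0.0017) up in WT1. Liver and intestine endoderm (0.0017), glycolysis and hypoxia (0.0017), mesenchyme and stellate (0.0089), imprinted (0.041) and lipid and cholesterol transport genes (0.049) were down. With an estimated correlation no list passed, and the lowest adjusted p was 0.083. List calls at the preset correlation thus also arose between sets of 1 genotype. Whether the libraries of a group come from separate clones, separate differentiations or repeats of 1 culture is not given in the sources used here, so what their spread measures is open, and beside each count stands the number of genes past the threshold in the same direction against WT1 alone and against WT2 alone. A comparison of group means (limma, 1 group against the other 21), chosen after seeing the data, called 0 genes in the knockouts of ABCC8, CDC123, COBLL1, GCKR and HTT, where 241, 491, 548, 257 and 567 genes had an unadjusted p under 0.05. Each of these counts is below 0.05 of the 21766 genes tested. The effects of the other knockouts add to the spread between groups that this test uses, so it can miss changes. The counts were also low in the knockouts of APOE (644), TGFB1 (228) and IGF2BP2 (175), whose targets fell, and in WT1 (230). A low count therefore does not show that a knockout had no effect.

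**Figure D2:**
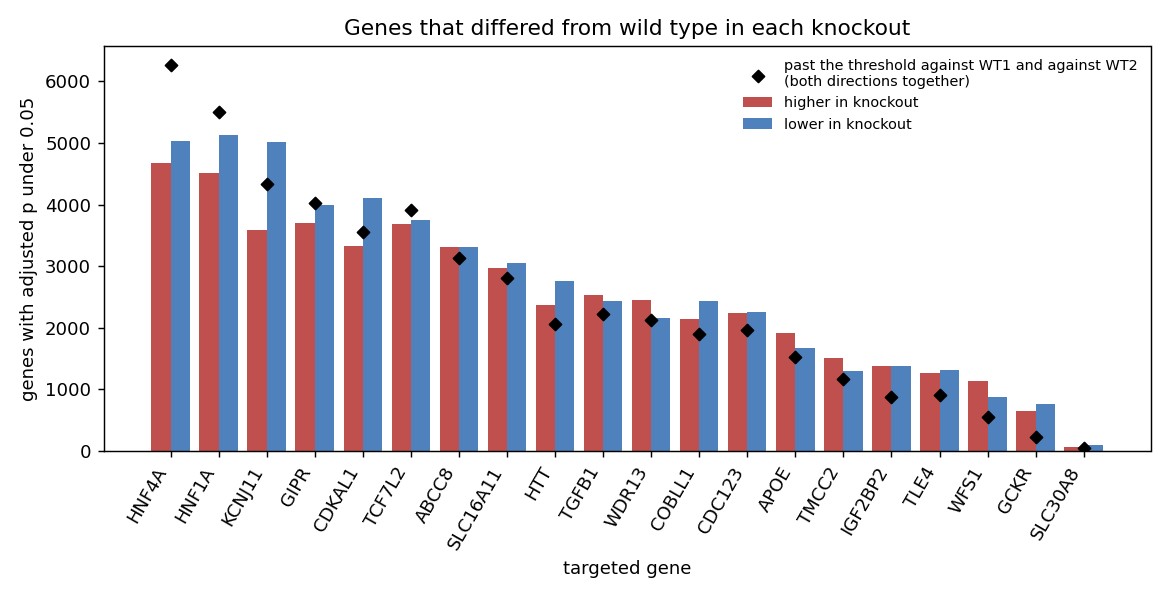
Genes with an adjusted p under 0.05 in each knockout against the 6 wild-type libraries, higher (red bars) and lower (blue bars), and the number past the threshold against WT1 and against WT2 in the same direction (black diamonds). HNF4A and HNF1A have 9697 and 9642 genes and SLC30A8 has 165.

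The endocrine genes themselves moved in several knockouts. In wild type GCG, the glucagon gene of alpha cells, was at 14800 ± 1800 CPM, SST, the somatostatin gene of delta cells, at 3720 ± 1200, INS at 1060 ± 380, and the beta cell transcription factors PDX1 and NKX6-1 at 142 ± 48 and 108 ± 15. The INS level is uncertain, because the gene overlaps INS-IGF2 and reads shared by the pair may be missing from the counts. NKX6-1 fell in 17 of the 20 knockouts, and in all 17 against WT1 and against WT2, although in the GCKR knockout it had an adjusted p of 0.10 or more without any 1 of the GCKR libraries. It was at 117 CPM in WT1 and 98.8 in WT2, with a median of 28.4 over the knockout libraries. As all knockouts share these controls, the 17 falls are not independent. A change seen in so many can lie in the wild-type libraries as much as in the knockouts, and the design does not separate these. PDX1 fell in 12, of which 3 (APOE, HNF4A and TCF7L2) passed against both. SST rose in 11 knockouts and fell in 3, with 7 and 2 against both. GCG rose in the knockouts of APOE, GIPR and TCF7L2 and fell in those of HNF1A, KCNJ11 and WDR13; the 3 rises passed against both wild-type sets, and of the falls only KCNJ11 did. INS rose in the knockouts of ABCC8, GIPR, SLC16A11 and TGFB1 and fell in that of KCNJ11, and only ABCC8 and KCNJ11 passed against both. With the GC and length trends of the libraries removed, a correction chosen after seeing the data, INS kept its call in SLC16A11 (adjusted p = 0.044) but had adjusted p of 0.05 in ABCC8, 0.84 in GIPR, 0.052 in TGFB1 and 0.66 in KCNJ11, and it passed as lower in HNF1A (-0.64, adjusted p = 0.0049), where it had not passed before. The same correction turned the sign of SST in GIPR and of PDX1 in KCNJ11, both counted above.

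**Figure D3:**
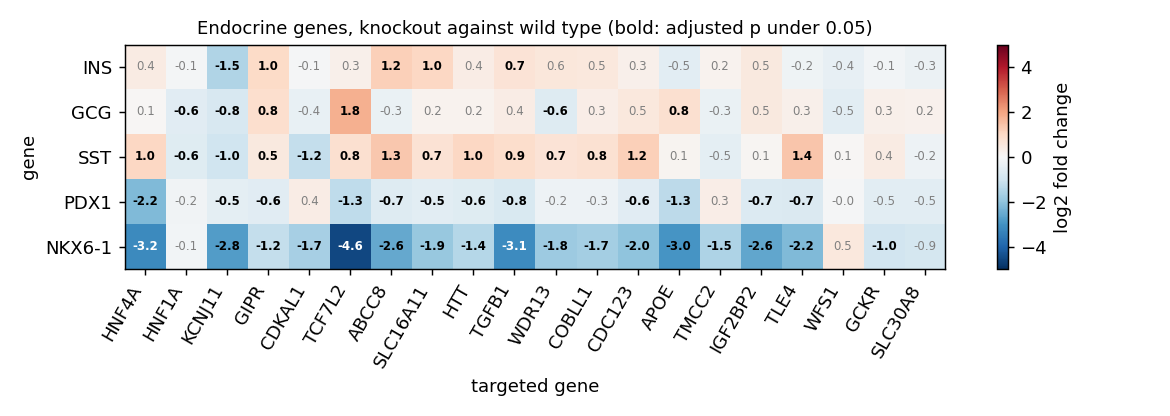
Log2 fold change of INS, GCG, SST, PDX1 and NKX6-1 in each knockout against wild type, printed in each cell and shown in colour (red higher, blue lower), in bold where the adjusted p was under 0.05. NKX6-1 is lower in 17 of 20 knockouts, lowest in TCF7L2 at -4.56.

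Of 620 tests of 31 fixed gene lists in the 20 knockouts, camera called 211, and 39 held with an estimated correlation. All knockouts share 6 controls, so recurrent calls are not independent and can lie in the controls. Delta, PP and epsilon cell genes were called up in 11 knockouts, 6 also with the estimated correlation, the largest number for any list. Counts with this estimate follow in brackets. TGF-beta and BMP target genes and cell cycle genes were each up in 12 (3 and 2). Cell cycle genes were down in 2 (0). Glycolysis and hypoxia genes were down in 11 (2) and up in 2 (0). Liver and intestine endoderm genes were up in 11 (1) and down in 5 (2). Pluripotency genes were up in 6 (4) and imprinted genes down in 9 (3). Among the lists with no call that held with the estimate, glucose sensing and excitability genes were down in 9, pancreatic progenitor and duct genes were up in 3, endocrine progenitor genes were up in 5 and down in 2, lipid and cholesterol transport genes were up in 3 and down in 1, and RNA and tRNA related translation genes were up in 2. Enterochromaffin-like cell genes were down in 10 (1). Zinc handling genes were called in none, where their lowest camera adjusted p was 0.065, in the COBLL1 knockout, and the 13 mitochondrially encoded genes had no counts in any library and were not tested.

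**Figure D4:**
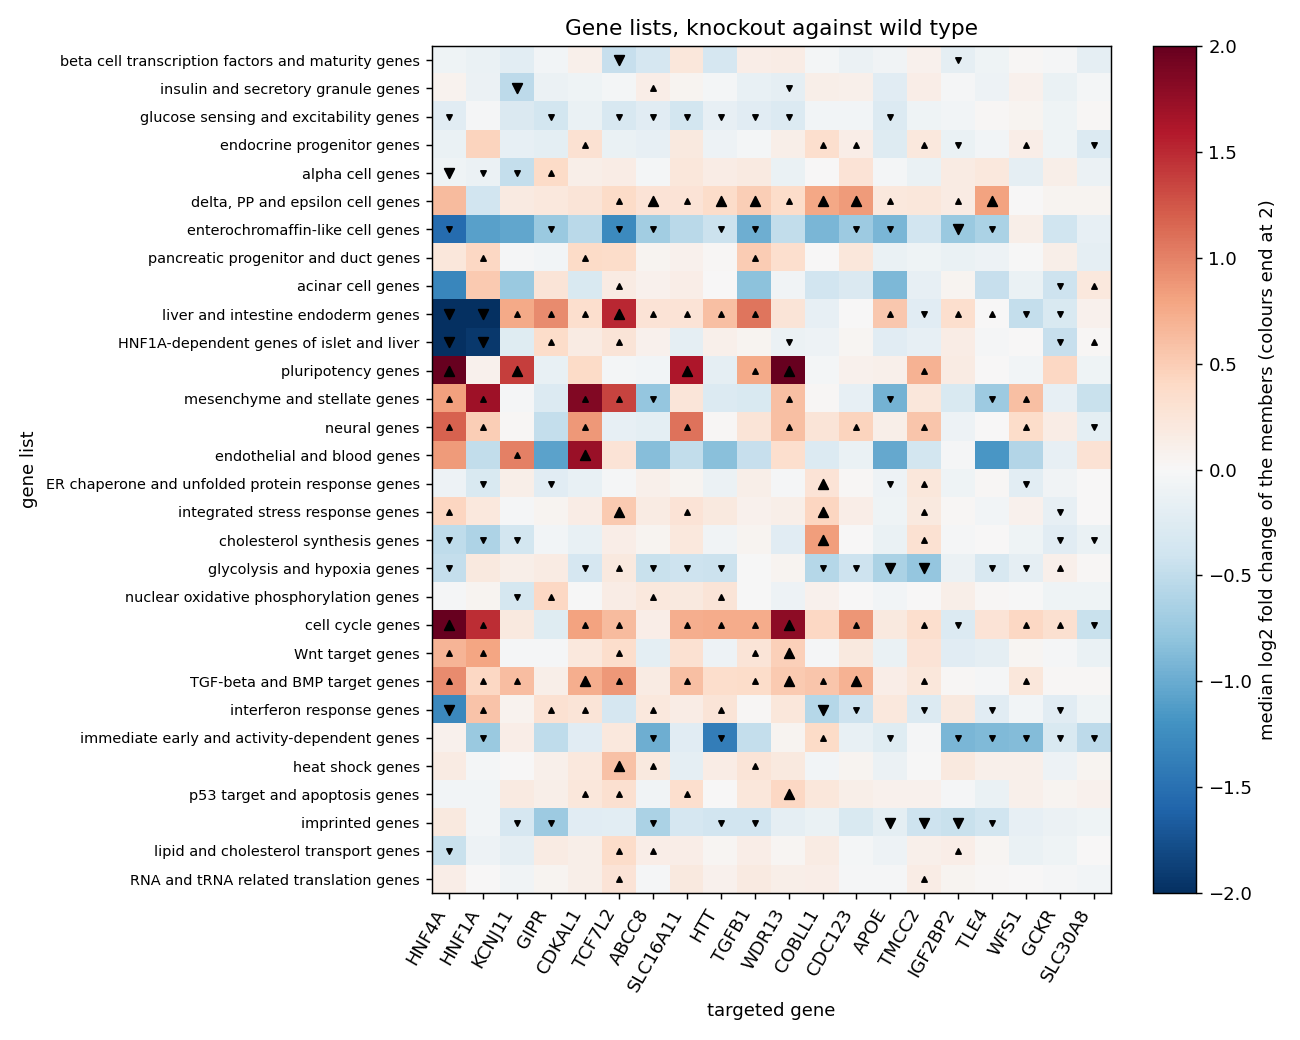
Median log2 fold change of the tested members of each list (rows) in each knockout (columns), in colour (red higher, blue lower, colours end at 2). Triangles point up or down where camera called the list at an adjusted p under 0.05, and the larger triangles, 39 in all, mark calls that held with an estimated correlation.

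HNF1A (ENSG00000135100, chromosome 12, 120978543 to 121002512, GRCh38) encodes a homeobox factor whose loss causes a monogenic diabetes. In its knockout SERPINA1, which encodes alpha-1-antitrypsin, fell from 5420 ± 480 to 134 ± 17 CPM (-5.34 ± 0.14, adjusted p = 1.7e-37), and SERPINA10 (-9.22 ± 0.19) and PKLR, the liver and red cell pyruvate kinase (-8.68 ± 0.32), fell to 0.14 ± 0.14 and 0.102 ± 0.099 CPM. SLC17A1, a phosphate transporter, had few counts left and was lower by a ratio of 1130 (95% Poisson interval 387 to 5490). CDH16 (-8.95 ± 0.38), ITIH1 (-8.71 ± 0.35), APOH (-8.25 ± 0.48), LIPC (-7.99 ± 0.31), the vitamin D carrier gene GC (-7.52 ± 0.55), TM4SF4 (-5.04 ± 0.19), DPP4 (-4.92 ± 0.21) and APOM (-3.97 ± 0.17) also fell, with adjusted p of 6.5e-17 or lower. Of the HNF1A-dependent genes of islet and liver, 25 of 29 fell and 1 rose (25 and 2 adjusted over the list alone; camera adjusted p = 1.7e-30, and 4.4e-06 with an estimated correlation). Of the liver and intestine endoderm genes, which share 3 members with that list, 22 of 26 fell (23 adjusted over the list alone; adjusted p = 1.0e-24, and 0.0016 with an estimated correlation).

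In the HNF1A knockout cell cycle genes rose in 27 of 28 members (27 adjusted over the list alone), among them E2F1 (2.16 ± 0.21), TPX2 (1.73 ± 0.17) and the replication helicase gene MCM7 (1.06 ± 0.11); the list's camera adjusted p was 1.2e-13, and adjusted p = 0.082 with an estimated correlation. Mesenchyme and stellate genes rose in 18 of 20 (18 adjusted over the list alone; adjusted p = 7.3e-08, and adjusted p = 0.15 with an estimated correlation). Members included SPARC at 221 ± 31 CPM against 37.9 ± 13 (2.54 ± 0.19), COL1A1 at 127 ± 31 against 32.9 ± 13 (1.95 ± 0.25) and POSTN at 19.9 ± 4.0 against 2.07 ± 0.79 (3.27 ± 0.34). The matrix genes THBS1 (2.98 ± 0.20) and CCN1 (2.66 ± 0.24) rose, and increases above 3 in log2 fold change included CEACAM6 (4.57 ± 0.33), the neuropeptide gene NPY (4.33 ± 0.31), ONECUT3 (3.78 ± 0.42) and TACSTD2 (3.59 ± 0.29). INS (-0.08 ± 0.27), PDX1 (-0.19 ± 0.18) and NKX6-1 (-0.14 ± 0.26) did not pass. In all 9642 genes passed, 4508 higher and 5134 lower, of which 5499 passed against both wild-type sets and 250 in the comparison of group means. Without HNF1A replicate 4 the count was 6384, and the slope of log2 CPM on GC share was 5.73 in that library.

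HNF4A (ENSG00000101076, chromosome 20, 44355700 to 44434596) encodes a nuclear receptor of liver, gut and islet. In its knockout 9697 genes passed, 4666 higher and 5031 lower; 6259 passed against both wild-type sets and 1205 in the comparison of group means, where 2263 did with the GC and length trends removed. APOA4 was at least 260-fold lower, FABP1 at least 254-fold and TM4SF5 at least 197-fold, each with 0 counts in the 3 libraries against 11.3 ± 7.3, 11.1 ± 4.3 and 8.59 ± 0.74 CPM. APOA4 ran from 4.16 to 19.7 CPM over the wild-type libraries and was lower in WT1 than in WT2, so its bound is smaller against WT1 alone. ANKS4B fell from 118 ± 12 to 0.0687 ± 0.063 CPM (-10.57 ± 0.19), APOB from 144 ± 29 to 0.30 ± 0.16 (-8.93 ± 0.36) and the villin gene VIL1 from 525 ± 79 to 21.4 ± 1.2 (-4.61 ± 0.13, adjusted p = 3e-36). SERPINA1 (-6.09 ± 0.14), AMBP (-5.27 ± 0.19), A1CF (-4.98 ± 0.16), PKLR (-8.87 ± 0.33) and TM4SF4 (-6.83 ± 0.21) fell too. Liver and intestine endoderm genes fell in 23 of 26 members and rose in 1 (24 and 1 adjusted over the list alone; adjusted p = 5.7e-47, and 4.4e-06 with an estimated correlation), and HNF1A-dependent genes fell in 25 of 29 and rose in 1 (25 and 1 adjusted over the list alone; adjusted p = 1.7e-35, and 8.4e-07).

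Cell cycle genes rose in 26 of 28 members in the HNF4A knockout (26 adjusted over the list alone; adjusted p = 8.4e-24, and 0.013 with an estimated correlation). Members included E2F1 (3.15 ± 0.21), BIRC5 (3.29 ± 0.26) and TPX2 (2.48 ± 0.16). Pluripotency genes rose in 11 of 14 (12 adjusted over the list alone; adjusted p = 1.3e-05, and 0.019 with an estimated correlation). Among them SOX2 rose from 8.36 ± 2.1 to 88.2 ± 3.8 CPM (3.39 ± 0.23), DNMT3B from 4.67 ± 1.0 to 17.2 ± 1.1 (1.86 ± 0.19) and L1TD1 from 0.357 ± 0.13 to 3.52 ± 0.18 (3.31 ± 0.34). Interferon response genes fell in 20 of 27 (20 adjusted over the list alone; adjusted p = 3.5e-08, and 0.019). Members included B2M (-1.86 ± 0.14), OAS1 (-2.91 ± 0.22) and MX1 (-2.62 ± 0.21). Increases above 4 in log2 fold change included the retinoic acid binding protein gene CRABP1, from 0.301 ± 0.26 to 62.3 ± 7.4 CPM (7.86 ± 0.55), KLHDC8A (6.31 ± 0.33), DCLK1 (6.13 ± 0.26), the gut hormone gene PYY (4.97 ± 0.32), ADGRG6 (4.75 ± 0.25) and TP63 (4.66 ± 0.36). PDX1 fell to 30.4 ± 0.89 CPM (-2.22 ± 0.20) and NKX6-1 to 11.8 ± 0.95 (-3.20 ± 0.31), while SST rose to 7640 ± 230 (1.04 ± 0.17). INS (0.40 ± 0.26) and GCG (0.06 ± 0.21) did not pass.

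HNF1A and HNF4A regulate each other in the pancreas, and the design allows their knockouts to be compared. Across 21766 genes their log2 fold changes correlated with r = 0.67 (genes are not independent replicates), rank 4 of the 190 pairs of knockouts. Unchanged groups simulated against the same 6 controls gave a mean r of 0.35, and the covariance was 0.992 against a simulated 0.0603, a difference of 0.932. The simulation drew all controls from 1 mean, without the difference between WT1 and WT2 or the GC trends. It can therefore understate the similarity that shared controls give. With the controls split, so that each knockout had its own wild-type set, r was 0.45 and 0.52. They shared 2770 higher genes, where independent lists of that size would share 966, and 2945 lower genes, where they would share 1187, with 268 called in opposite directions. Directly compared, 5758 genes differed, 2759 higher and 2999 lower in the HNF1A knockout; without HNF1A replicate 4 the count was 3581. APOA4 and TM4SF5 were at least 210-fold and at least 36.3-fold higher in the HNF1A knockout, and AHSG was at 8.75 ± 1.3 against 0.0604 ± 0.033 CPM (7.13 ± 0.93). NKX6-1 (3.05 ± 0.33) and PDX1 (2.03 ± 0.21) were higher there, and PYY (-5.66 ± 0.44), CRABP1 (-4.57 ± 0.55) and SST (-1.64 ± 0.21) were lower.

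KCNJ11 (ENSG00000187486, chromosome 11, 17385248 to 17389331) encodes the pore of the ATP-sensitive potassium channel that couples glucose to insulin secretion. In its knockout 8598 genes passed, 3582 higher and 5016 lower, and 4327 against both wild-type sets. Log2 fold changes correlated with GC share across genes (r = -0.68), and the slopes of log2 CPM on GC share in replicates 2 and 3 were -6.15 and -8.57. With the GC and length trends removed 6494 genes passed, 4454 of them in both fits in the same direction and 150 in the opposite one, and the count in the comparison of group means went from 1525 to 1. Without KCNJ11 replicate 3 the count was 5731. Secretory granule genes fell in 18 of 29 members and rose in 2 (18 and 2 adjusted over the list alone; adjusted p = 2.6e-05, and 0.038 with an estimated correlation). CHGA, the chromogranin A gene, was at 15600 ± 3700 CPM against 38300 ± 3800 (-1.29 ± 0.17, adjusted p = 2.2e-08), PCSK1N at 15.7 ± 13 against 156 ± 56 (-3.32 ± 0.45) and SCG2 at 157 ± 48 against 367 ± 44 (-1.23 ± 0.13). INS was at 377 ± 6.7 CPM (-1.49 ± 0.29), but at -0.13 with the trends removed. SST (-1.0 ± 0.19) and NKX6-1 (-2.78 ± 0.31) fell. KCNJ11 itself had 42.6 ± 22 CPM and a change of -0.05 (adjusted p = 0.76) with the trends removed, -0.31 (adjusted p = 0.17) without replicate 3 and -0.42 (adjusted p = 0.055) against WT2 alone.

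Pluripotency genes rose in 10 of 14 members in the KCNJ11 knockout (10 adjusted over the list alone; adjusted p = 1.4e-04, and 0.039 with an estimated correlation). Members included SOX2 (1.63 ± 0.23), TRIM71 (1.28 ± 0.14) and DPPA4 (1.42 ± 0.27). Liver and intestine endoderm genes rose in 13 of 26 and fell in 7 (14 and 8 adjusted over the list alone; adjusted p = 0.021), but with adjusted p = 0.52 with an estimated correlation, 0.51 against WT2 alone, and 0.053 and 0.066 without WT1 replicate 1 or 3. APOB rose from 144 ± 29 to 598 ± 30 CPM (2.05 ± 0.18), CDH17 (1.73 ± 0.22) and MTTP (1.12 ± 0.15) rose, and the plasma protein gene AHSG rose (2.86 ± 0.35). Nuclear oxidative phosphorylation genes fell in 20 of 32 and rose in 1 (20 and 2 adjusted over the list alone; adjusted p = 4.8e-04, and adjusted p = 0.41 with an estimated correlation). Members included NDUFA2 (-0.88 ± 0.13), NDUFS8 (-1.20 ± 0.21) and UQCRQ (-0.90 ± 0.15). Other changes included the imprinted RNA gene H19, lower by a ratio of 1340 (95% Poisson interval 240 to 52900), and CHCHD2 at 0.953 ± 0.28 against 44.0 ± 5.2 CPM (-5.54 ± 0.21). The serotonin synthesis gene TPH1 fell (-3.45 ± 0.51), and MUC16 (5.13 ± 0.51), CRABP1 (4.22 ± 0.62) and the titin gene TTN (2.82 ± 0.25) rose. H19, CHCHD2 and TPH1 fell and CRABP1 rose in other knockouts as well, so these changes are not particular to this one.

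**Figure D5:**
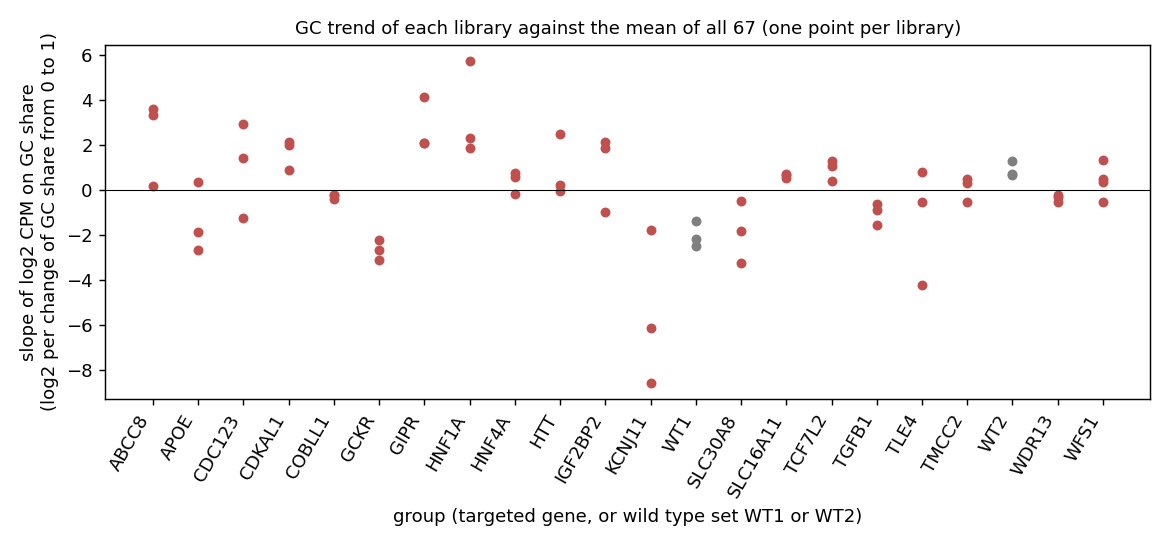
Slope of log2 CPM on the GC share of transcripts in each of the 67 libraries, against the mean of all libraries, 1 point per library, for the knockouts (red) and for WT1 and WT2 (grey). KCNJ11 replicates 2 and 3 have the lowest slopes, -6.15 and -8.57, and HNF1A replicate 4 the highest, 5.73.

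ABCC8 (ENSG00000006071, chromosome 11, 17392498 to 17476879) encodes the regulatory subunit of the same channel. In its knockout 6627 genes passed, 3317 higher and 3310 lower, and 3139 against both wild-type sets. Without ABCC8 replicate 2 the count was 3805. Log2 fold changes correlated with GC share (r = 0.5), and the slopes on GC share were 3.59, 3.31 and 0.19 in replicates 1, 2 and 3. With the GC and length trends removed 5758 genes passed, 4188 of them in both fits in the same direction. SST was at 9410 ± 1200 CPM (1.34 ± 0.17, adjusted p = 2.7e-08) and INS at 2440 ± 750 (1.20 ± 0.26). Delta, PP and epsilon cell genes rose in 7 of 17 (7 adjusted over the list alone; adjusted p = 7.8e-06, and 0.0023 with an estimated correlation). Members included RBP4 (2.36 ± 0.24), LEPR (2.15 ± 0.26) and AQP3 (1.46 ± 0.12). Secretory granule genes rose in 11 of 29 and fell in 4 (11 and 4 adjusted over the list alone; adjusted p = 0.0099, and adjusted p = 0.21 with an estimated correlation). Members included VGF (2.05 ± 0.24) and CHGB (1.13 ± 0.15). Immediate early genes fell in 14 of 25 and rose in 1 (15 and 1 adjusted over the list alone; adjusted p = 6.2e-05, and adjusted p = 0.38 with an estimated correlation). Members included EGR1 at 284 ± 47 against 1200 ± 270 CPM (-2.08 ± 0.22) and FOS (-1.87 ± 0.27). Glycolysis and hypoxia genes fell in 18 of 30 and rose in 2 (19 and 2 adjusted over the list alone; adjusted p = 5.8e-06, and adjusted p = 0.25 with an estimated correlation). Members included NDRG1 (-1.30 ± 0.17), PDK1 (-1.33 ± 0.18) and LDHA (-0.90 ± 0.13). PYY (3.91 ± 0.32), SPON2 (2.99 ± 0.27) and APOE (1.60 ± 0.25) rose, and CHCHD2 (-9.68 ± 0.30) and NKX6-1 (-2.56 ± 0.30) fell.

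The fold changes of the ABCC8 and KCNJ11 knockouts, in which the 2 subunits of 1 channel were targeted, correlated with r = 0.09 across genes, rank 179 of the 190 pairs, where unchanged groups simulated against the same controls gave 0.35. The covariance was 0.0622 against a simulated 0.0594, and r was -0.21 and -0.09 with the controls split. This simulation also left out the difference between WT1 and WT2 and the GC trends, so its values are not a full reference. They shared 369 higher genes (546 for independent lists) and 538 lower genes (763), and 2723 genes were called in opposite directions. With the GC and length trends removed they shared 646 (379) and 678 (482), with 1153 opposite. Against WT2 alone they shared 830 (610) and 868 (728), and against WT1 alone 352 (371) and 545 (644). Whether the overlap lay below or above that of independent lists thus depended on the correction and the control. With the GC and length trends removed r was 0.24, and against WT1 alone and WT2 alone it was 0.18 and 0.38. Directly compared, 11024 genes differed, 5515 higher and 5509 lower in the ABCC8 knockout, and log2 fold changes correlated with GC share (r = 0.74); 8183 genes differed with the trends removed, 522 of those called in both fits in the opposite direction. PCSK1N (5.41 ± 0.52), PYY (5.09 ± 0.44), INS (2.69 ± 0.33) and SST (2.34 ± 0.22) were higher in the ABCC8 knockout, and FOSB (-5.81 ± 0.82) and CALB2 (-5.69 ± 0.48) were lower. With the trends removed INS was at 0.59 (adjusted p = 0.024), SST at 1.54, PCSK1N at 3.26 and PYY at 4.07. GCG, PDX1 and NKX6-1 did not pass.

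GIPR (ENSG00000010310, chromosome 19, 45668221 to 45683722) encodes the receptor of the incretin GIP. In its knockout 7690 genes passed, 3701 higher and 3989 lower, and 4022 against both wild-type sets. Log2 fold changes correlated with GC share (r = 0.57) and with transcript length (r = -0.53), and 5839 genes passed with the trends removed, 3866 of them in both fits in the same direction. GCG was at 26600 ± 3700 CPM (0.84 ± 0.21, adjusted p = 0.0011). Alpha cell genes rose in 9 of 18 and fell in 1 (10 and 2 adjusted over the list alone; adjusted p = 0.0086, and adjusted p = 0.071 with an estimated correlation). Members included the transthyretin gene TTR at 37400 ± 2300 against 17700 ± 2600 CPM (1.08 ± 0.16), PEMT (1.21 ± 0.18) and F10 (0.83 ± 0.14). Liver and intestine endoderm genes rose in 18 of 26 and fell in 1 (18 and 1 adjusted over the list alone; adjusted p = 2.4e-09, and adjusted p = 0.074 with an estimated correlation). Members included APOA4 at 114 ± 49 against 11.3 ± 7.3 CPM (3.32 ± 0.34), FGG (1.92 ± 0.29) and APOM (1.13 ± 0.12).

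Nuclear oxidative phosphorylation genes rose in 22 of 32 and fell in 2 in the GIPR knockout (23 and 2 adjusted over the list alone; adjusted p = 2.6e-08, and adjusted p = 0.15 with an estimated correlation). Members included CYC1 (1.10 ± 0.13), COX5B (1.21 ± 0.16) and NDUFA2 (0.86 ± 0.12). The list was up in GIPR, ABCC8 and HTT (r with GC share 0.57, 0.5 and 0.3) and down in KCNJ11 (-0.68). Without a call r ran from -0.57 in GCKR to 0.44 in HNF1A, so the signs do not decide on a GC bias. Of 70 list calls followed through the alternatives, 68 held with the trends removed. Interferon response genes rose in 11 of 27 and fell in 3 (12 and 3 adjusted over the list alone; adjusted p = 0.0011, and adjusted p = 0.17 with an estimated correlation); the antigen presentation genes HLA-A (1.26 ± 0.13), HLA-B (1.36 ± 0.15) and HLA-C (1.21 ± 0.15) led them, and reads can be shared among these near-identical genes. ER chaperone and unfolded protein response genes fell in 12 of 26 and rose in 3 (13 and 4 adjusted over the list alone; adjusted p = 0.0028, but 0.054 against WT1 alone, and adjusted p = 0.24 with an estimated correlation). Members included EDEM1 (-0.92 ± 0.08), ERN1 (-0.89 ± 0.11) and HSPA5 at 1290 ± 100 against 2070 ± 200 CPM (-0.69 ± 0.09). Low log2 fold changes included ZNF93 (-7.45 ± 0.34), ZNF37A (-4.82 ± 0.50), OXCT1 (-4.50 ± 0.48) and GLUD2 (-4.15 ± 0.23), the last of which alone passed in the comparison of group means. ZNF37A was at -3.27 against WT1 alone and -5.54 against WT2 alone, and OXCT1 at -2.74 and -5.25. Increases included TFF1 (2.52 ± 0.32), GSTA2 (2.44 ± 0.28), AHSG (2.38 ± 0.35) and the secretin gene SCT (2.31 ± 0.36). NKX6-1 fell (-1.19 ± 0.28).

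CDKAL1 (ENSG00000145996, chromosome 6, 20534457 to 21232404) encodes a tRNA-modifying enzyme. In its knockout 7444 genes passed, 3332 higher and 4112 lower, 3555 against both wild-type sets and 100 in the comparison of group means. Mesenchyme and stellate genes rose in 15 of 20 (15 adjusted over the list alone; adjusted p = 4.8e-12, and adjusted p = 0.054 with an estimated correlation). SPARC was at 125 ± 11 against 37.9 ± 13 CPM (1.71 ± 0.19), COL1A1 at 108 ± 12 against 32.9 ± 13 (1.70 ± 0.25) and COL6A3 at 14.4 ± 3.9 against 2.61 ± 0.89 (2.45 ± 0.35), and the matrix protease gene MMP2 rose as well (3.15 ± 0.32). TGF-beta and BMP target genes rose in 14 of 21 and fell in 1 (15 and 2 adjusted over the list alone; adjusted p = 2.0e-08, and 0.019 with an estimated correlation). Members included ID2 (1.42 ± 0.16), SMAD7 (1.42 ± 0.18) and TGFBI (2.05 ± 0.26). Endothelial and blood genes rose in 6 of 9 (7 adjusted over the list alone; adjusted p = 4.0e-04, and 0.042). CD34 was at 0.88 ± 0.30 against 0.0475 ± 0.06 CPM (3.75 ± 0.68) and PECAM1 at 2.48 ± 0.78 against 0.48 ± 0.35 (2.37 ± 0.46).

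Cell cycle genes rose in 21 of 28 members in the CDKAL1 knockout (21 adjusted over the list alone; adjusted p = 7.1e-11, and adjusted p = 0.11 with an estimated correlation). Members included E2F1 (1.67 ± 0.22), BIRC5 (1.76 ± 0.28) and FOXM1 (1.72 ± 0.27). The p53 target and apoptosis genes rose in 9 of 22 and fell in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.016, but 0.10 against WT1 alone, and adjusted p = 0.15 with an estimated correlation). Members included the cell cycle inhibitor gene CDKN1A (1.19 ± 0.17), PHLDA3 (1.71 ± 0.27) and TNFRSF10B (0.76 ± 0.14). SST fell to 1620 ± 63 CPM (-1.20 ± 0.19, adjusted p = 2.5e-06) and NKX6-1 to 34.2 ± 7.8 (-1.66 ± 0.29), while INS (-0.07 ± 0.27), GCG (-0.36 ± 0.22) and PDX1 (0.37 ± 0.17) did not pass. TPH1 (-3.28 ± 0.52), CHCHD2 (-2.80 ± 0.17) and the long non-coding RNA gene MIAT (-2.55 ± 0.35) fell, and the developmental regulators PITX1 (2.86 ± 0.30) and TBX3 (2.66 ± 0.28) rose. TPH1 and MIAT were each lower in 16 of the 20 knockouts, so their falls are not particular to this one.

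In the TCF7L2 knockout (ENSG00000148737, chromosome 10, 112950247 to 113167678), of a transcription factor of the Wnt pathway, 7434 genes passed, 3681 higher and 3753 lower, 3903 against both wild-type sets and 30 in the comparison of group means. GCG was at 51000 ± 7700 CPM (1.78 ± 0.21, adjusted p = 5.6e-10). Beta cell transcription factor and maturity genes fell in 10 of 23 and rose in 2 (10 and 3 adjusted over the list alone; adjusted p = 4.8e-04, and 0.046 with an estimated correlation). Members included NKX6-1 at 4.6 ± 1.4 CPM (-4.56 ± 0.35), MEIS2 (-1.75 ± 0.15), DLK1 (-2.88 ± 0.31) and PDX1 (-1.27 ± 0.19). Liver and intestine endoderm genes rose in 17 of 26 (18 adjusted over the list alone, with 1 lower; adjusted p = 8.1e-15, and 0.020). Members included FGB at 4270 ± 1500 against 453 ± 150 CPM (3.24 ± 0.28), FGG (3.52 ± 0.29) and CDH17 (2.99 ± 0.22). Heat shock genes rose in 10 of 15 (10 adjusted over the list alone, with 1 lower; adjusted p = 2.1e-09, and 0.030). Members included HSPA6 at 72.2 ± 30 against 0.417 ± 0.18 CPM (7.52 ± 0.54), DNAJB1 (1.76 ± 0.12) and HSPA1B (2.54 ± 0.19). Integrated stress response genes rose in 19 of 29 and fell in 1 (20 and 1 adjusted over the list alone; adjusted p = 2.4e-07, and 0.022). Members included GDF15 (2.63 ± 0.23), PSAT1 (2.60 ± 0.21) and MTHFD2 (1.26 ± 0.13). The trypsinogen genes PRSS2 at 595 ± 340 CPM (4.52 ± 0.30) and PRSS1 at 154 ± 69 (4.27 ± 0.27) rose, and reads can be shared between them. SOX2 (-4.57 ± 0.41) and CHCHD2 (-4.72 ± 0.20) fell, and CD8B rose (4.33 ± 0.29).

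In the knockout of WDR13 (ENSG00000101940, chromosome X, 48590042 to 48608869), a WD-repeat gene, 4609 genes passed, 2444 higher and 2165 lower, 2119 against both wild-type sets and 34 in the comparison of group means. Pluripotency genes rose in 13 of 14 (13 adjusted over the list alone; adjusted p = 1.0e-31, and 4.2e-09 with an estimated correlation). L1TD1 was at 6.53 ± 1.5 against 0.357 ± 0.13 CPM (4.2 ± 0.33), LIN28A at 54.4 ± 0.77 against 15.9 ± 4.6 (1.78 ± 0.15) and DNMT3B at 22.8 ± 0.92 against 4.67 ± 1.0 (2.27 ± 0.19). Cell cycle genes rose in 24 of 28 (25 adjusted over the list alone; adjusted p = 6.7e-33, and 0.0021). Members included TOP2A (2.49 ± 0.27), BIRC5 (2.46 ± 0.27) and TPX2 (1.99 ± 0.16). Wnt target genes rose in 11 of 21 and fell in 1 (14 and 1 adjusted over the list alone; adjusted p = 3.0e-05, and 0.031). Members included LGR5 (3.81 ± 0.67) and LEF1 (3.34 ± 0.55). The p53 target genes rose in 10 of 22 and fell in 1 (10 and 1 adjusted over the list alone; adjusted p = 4.2e-05, and 0.012). Members included BBC3 (1.43 ± 0.21) and TNFRSF10B (0.99 ± 0.13). CRABP1 (8.10 ± 0.55), OTX2 (4.03 ± 0.46) and the neural progenitor gene NES (3.31 ± 0.43) rose, NKX6-1 fell (-1.82 ± 0.29), and ZNF285 was at least 78.1-fold lower.

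In the knockout of SLC16A11 (ENSG00000174326, chromosome 17, 7041621 to 7044092), which encodes a monocarboxylate transporter, 6017 genes passed, 2968 higher and 3049 lower, and 2801 against both wild-type sets. Pluripotency genes rose in 11 of 14 (12 adjusted over the list alone; adjusted p = 5.0e-08, and 0.0023 with an estimated correlation). ESRG was at least 113-fold higher, POU5F1 higher by a ratio of 71.8 (95% Poisson interval 19.9 to 593), at 1.17 ± 0.93 CPM, and SOX2 was at 27.2 ± 12 CPM (1.70 ± 0.23). Neural genes rose in 12 of 21 and fell in 2 (13 and 3 adjusted over the list alone; adjusted p = 1.8e-04, and adjusted p = 0.17 with an estimated correlation). Members included PHOX2B higher by a ratio of 180 (49.9 to 1490), NEFL at 34.6 ± 29 against 4.70 ± 1.8 CPM (2.90 ± 0.35) and GAP43 (2.38 ± 0.22). Glycolysis and hypoxia genes fell in 18 of 30 and rose in 1 (19 and 1 adjusted over the list alone; adjusted p = 1.7e-07, and adjusted p = 0.17 with an estimated correlation). Members included HK2 (-1.82 ± 0.21), NDRG1 (-1.53 ± 0.17) and GPI (-0.85 ± 0.12). CRABP1 (8.99 ± 0.55) and TP63 (4.10 ± 0.37) rose, and APLN (-3.06 ± 0.34), DRAIC (-2.89 ± 0.32) and NKX6-1 (-1.90 ± 0.29) fell.

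In the HTT knockout (ENSG00000197386, chromosome 4, 3041363 to 3243960), of the huntingtin gene, 5124 genes passed, 2368 higher and 2756 lower, and 2069 against both wild-type sets. Immediate early genes fell in 19 of 25 (19 adjusted over the list alone, with 1 higher; adjusted p = 1.6e-13, and adjusted p = 0.076 with an estimated correlation). Members included EGR1 at 236 ± 13 against 1200 ± 270 CPM (-2.35 ± 0.23), FOS at 222 ± 22 against 1100 ± 450 (-2.31 ± 0.27) and DUSP1 (-1.85 ± 0.22). Delta, PP and epsilon cell genes rose in 8 of 17 (8 adjusted over the list alone; adjusted p = 1.2e-06, and 0.0014). Members included SST at 7520 ± 880 CPM (1.02 ± 0.17), RBP4 (1.77 ± 0.24) and AQP3 (1.31 ± 0.12). Glycolysis and hypoxia genes fell in 18 of 30 (21 adjusted over the list alone; adjusted p = 9.2e-08, and adjusted p = 0.17 with an estimated correlation). Members included PDK1 (-1.23 ± 0.18), P4HA1 (-1.19 ± 0.16) and NDRG1 (-1.06 ± 0.16). TXNRD2 (-6.10 ± 0.26) and ZNF793 (-5.85 ± 0.42) fell, and ATP12A (3.50 ± 0.32) and FLT1 (2.66 ± 0.33) rose.

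In the TGFB1 knockout (ENSG00000105329, chromosome 19, 41301587 to 41353922), of a secreted growth factor, 4975 genes passed, 2538 higher and 2437 lower, and 2222 against both wild-type sets; the lowest count with a library left out was 3312. Delta, PP and epsilon cell genes rose in 9 of 17 and fell in 3 (9 and 3 adjusted over the list alone; adjusted p = 6.0e-06, and 0.0023 with an estimated correlation). Members included RBP4 at 430 ± 25 against 61.8 ± 17 CPM (2.80 ± 0.24), LEPR (2.42 ± 0.26) and SST (0.89 ± 0.17). Liver and intestine endoderm genes rose in 14 of 26 and fell in 4 (17 and 5 adjusted over the list alone; adjusted p = 3.5e-08, and adjusted p = 0.11 with an estimated correlation). Members included AFP at 2340 ± 150 against 299 ± 99 CPM (2.97 ± 0.28), FGA (2.83 ± 0.32) and APOB (1.59 ± 0.18). TGF-beta and BMP target genes rose in 9 of 21 and fell in 1 (11 and 1 adjusted over the list alone; adjusted p = 0.011). Members included BMP2 (1.23 ± 0.17) and ID4 (1.24 ± 0.21); the list had adjusted p = 0.31 with an estimated correlation, 0.21 against WT1 alone, 0.052 in a fit of the knockout and wild type alone and 0.13 with the trends removed. CRABP1 (6.91 ± 0.55) and A2M (3.67 ± 0.27) rose, and MGMT (-7.65 ± 0.50) and NKX6-1 (-3.14 ± 0.31) fell. MAGEH1 was lower than in the 6 wild-type libraries by a ratio of 255 (95% Poisson interval 70.6 to 2100), but wild type was at 1.11 ± 0.019 CPM in WT1 and 13 ± 3.0 in WT2, and the log2 fold change was -5.09 against WT1 alone and -8.62 against WT2 alone.

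In the COBLL1 knockout (ENSG00000082438, chromosome 2, 164653624 to 164843679), of an actin-binding protein gene, 4593 genes passed, 2150 higher and 2443 lower, and 1902 against both wild-type sets; the lowest count with a library left out was 2815. Cholesterol synthesis genes rose in 20 of 24 (21 adjusted over the list alone; adjusted p = 2.1e-15, and 0.038 with an estimated correlation). Members included HMGCS1 at 1130 ± 12 against 409 ± 60 CPM (1.47 ± 0.16), SQLE (0.91 ± 0.12) and PCSK9 (1.5 ± 0.21). ER chaperone and unfolded protein response genes rose in 13 of 26 (20 adjusted over the list alone; adjusted p = 3.4e-07, and 0.042). Members included SDF2L1 (1.06 ± 0.20), CRELD2 (0.62 ± 0.13) and XBP1 (0.49 ± 0.10). Integrated stress response genes rose in 16 of 29 and fell in 2 (16 and 2 adjusted over the list alone; adjusted p = 8.3e-06, and 0.046). Members included SLC7A11 (1.46 ± 0.24), TRIB3 (1.09 ± 0.15) and MTHFD2 (1.07 ± 0.13). Interferon response genes fell in 14 of 27 (15 adjusted over the list alone; adjusted p = 1.8e-06, and 0.042). Members included IFIT1 (-1.35 ± 0.23), IRF1 (-0.85 ± 0.13) and PSMB8 (-0.81 ± 0.16). PYY (3.76 ± 0.32) and ANXA1 (2.93 ± 0.34) rose, NLRP2 fell from 71.6 ± 6.6 to 2.28 ± 0.48 CPM (-4.98 ± 0.12), and ZNF93, with 0 counts, was at least 195-fold lower.

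In the CDC123 knockout (ENSG00000151465, chromosome 10, 12195965 to 12250589), of a translation initiation factor assembly gene, 4494 genes passed, 2234 higher and 2260 lower, and 1962 against both wild-type sets; the lowest count with a library left out was 2841. Delta, PP and epsilon cell genes rose in 10 of 17 (10 adjusted over the list alone; adjusted p = 3.6e-08, and 2.9e-04 with an estimated correlation). Members included SST at 8530 ± 1500 CPM (1.20 ± 0.17) and AQP3 (1.52 ± 0.12). TGF-beta and BMP target genes rose in 12 of 21 and fell in 1 (12 and 1 adjusted over the list alone; adjusted p = 1.8e-06, and 0.046). Members included SMAD7 (1.30 ± 0.18), THBS1 (1.19 ± 0.21) and TGFB1 (0.87 ± 0.16). Cell cycle genes rose in 18 of 28 (23 adjusted over the list alone; adjusted p = 2.8e-09, and adjusted p = 0.15 with an estimated correlation). Members included FOXM1 (1.57 ± 0.27) and E2F1 (1.10 ± 0.22). PYY (4.18 ± 0.32), DCLK1 (4.13 ± 0.26) and RELN (3.07 ± 0.30) rose, and TF at 3.60 ± 0.077 against 137 ± 130 CPM (-5.25 ± 0.65, with -2.09 against WT1 alone and -6.17 against WT2 alone), ZBED6CL (-5.18 ± 0.42) and NKX6-1 (-2.03 ± 0.29) fell.

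In the APOE knockout (ENSG00000130203, chromosome 19, 44905791 to 44909393), 3582 genes passed, 1916 higher and 1666 lower, and 1531 against both wild-type sets; the lowest count with a library left out was 2290. Glycolysis and hypoxia genes fell in 20 of 30 (24 adjusted over the list alone, with 1 higher; adjusted p = 5.8e-15, and 0.040 with an estimated correlation). Members included LDHA (-1.04 ± 0.13), NDRG1 (-1.16 ± 0.16) and TPI1 (-0.97 ± 0.14). Mesenchyme and stellate genes fell in 9 of 20 and rose in 1 (11 and 1 adjusted over the list alone; adjusted p = 2.2e-05, and adjusted p = 0.25 with an estimated correlation). Members included COL3A1 (-4.22 ± 0.44) and COL1A2 (-2.16 ± 0.25). Imprinted genes fell in 7 of 22 and rose in 3 (7 and 3 adjusted over the list alone; adjusted p = 0.0045, and 0.046). Members included DLK1 (-2.84 ± 0.30) and H19, which had 0 counts and was at least 1220-fold lower. GCG was at 25800 ± 650 CPM (0.80 ± 0.21), and PDX1 (-1.29 ± 0.19) and NKX6-1 (-2.95 ± 0.30) fell. ATP12A (3.46 ± 0.32), BHMT2 (3.38 ± 0.27) and AFP (2.31 ± 0.28) rose, and ZNF93 (-7.93 ± 0.32), TXNRD2 (-6.63 ± 0.23) and NLRP2 (-4.90 ± 0.11) fell.

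In the TMCC2 knockout (ENSG00000133069, chromosome 1, 205227946 to 205285632), of a transmembrane coiled-coil protein gene, 2808 genes passed, 1504 higher and 1304 lower, and 1163 against both wild-type sets; the lowest count with a library left out was 1821. Glycolysis and hypoxia genes fell in 20 of 30 (22 adjusted over the list alone; adjusted p = 1.0e-24, and 0.0044 with an estimated correlation). Members included NDRG1 at 86.4 ± 26 against 360 ± 82 CPM (-2.06 ± 0.17), HK2 (-1.93 ± 0.21) and BNIP3 (-0.96 ± 0.11). Imprinted genes fell in 5 of 22 and rose in 2 (8 and 3 adjusted over the list alone; adjusted p = 0.0025, and 0.038 with an estimated correlation, but 0.061 against WT1 alone). Members included H19 at least 398-fold lower, DLK1 (-1.66 ± 0.28) and PLAGL1 (-0.87 ± 0.12). H19 ran from 7.44 to 37.5 CPM over the wild-type libraries and was lower in WT1 than in WT2, so its bound is smaller against WT1 alone. Neural genes rose in 11 of 21 and fell in 2 (11 and 3 adjusted over the list alone; adjusted p = 0.0030, with adjusted p = 0.29 with an estimated correlation, 0.063 against WT1 alone, 0.12 in a fit of the knockout and wild type alone and 0.10 without TMCC2 replicate 4). The neural crest genes SOX10, at least 255-fold higher at 6.21 ± 8.6 CPM, and PAX3, at least 92.6-fold higher at 2.26 ± 2.7, varied widely between libraries. SOX10 ran from 1.19 to 16.1 CPM and PAX3 from 0.495 to 5.37, so these bounds, taken from the means, rest largely on the highest library. CRABP1 (7.92 ± 0.55) and TP63 (3.76 ± 0.37) rose, CHCHD2 was lower by a ratio of 913 (95% Poisson interval 312 to 4430), and NKX6-1 fell (-1.53 ± 0.28).

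In the IGF2BP2 knockout (ENSG00000073792, chromosome 3, 185643130 to 185825042), of an RNA-binding protein gene, 2763 genes passed, 1388 higher and 1375 lower, and 875 against both wild-type sets; without IGF2BP2 replicate 2 the count was 1235. Imprinted genes fell in 8 of 22 (10 adjusted over the list alone; adjusted p = 2.0e-05, and 0.0025 with an estimated correlation). Members included DLK1 (-2.26 ± 0.29), MEST (-0.60 ± 0.09) and H19, lower by a ratio of 1440 (95% Poisson interval 258 to 56900). Enterochromaffin-like cell genes fell in 9 of 14 (10 adjusted over the list alone, with 1 higher; adjusted p = 4.2e-06, and 0.039). Members included TPH1 at 1.84 ± 0.48 against 16.8 ± 9.5 CPM (-3.16 ± 0.50) and the monoamine transporter gene SLC18A1 (-2.37 ± 0.33). NKX6-1 (-2.58 ± 0.30) and CHCHD2 (-2.55 ± 0.16) fell, and ACP5 (2.51 ± 0.25) and SPON2 (2.08 ± 0.27) rose.

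In the TLE4 knockout (ENSG00000106829, chromosome 9, 79571773 to 79726882), of a transcriptional corepressor, 2577 genes passed, 1268 higher and 1309 lower, and 906 against both wild-type sets; the lowest count with a library left out was 1611. Delta, PP and epsilon cell genes rose in 10 of 17 (10 adjusted over the list alone; adjusted p = 2.4e-12, and 4.2e-06 with an estimated correlation). Members included SST at 9620 ± 1500 CPM (1.37 ± 0.17), AQP3 (1.11 ± 0.12) and ETV1 (0.96 ± 0.14). Mesenchyme and stellate genes fell in 8 of 20 (9 adjusted over the list alone; adjusted p = 6.8e-06, and adjusted p = 0.22 with an estimated correlation). Members included COL3A1 (-3.71 ± 0.45) and COL1A2 (-1.76 ± 0.25). Immediate early genes fell in 13 of 25 (18 adjusted over the list alone, with 2 higher; adjusted p = 2.8e-08, and adjusted p = 0.19 with an estimated correlation). Members included NPAS4 (-2.66 ± 0.45), NR4A2 (-2.07 ± 0.37) and EGR1 (-1.20 ± 0.21). RELN (3.01 ± 0.30) and CYGB (2.70 ± 0.26) rose, and TF (-5.68 ± 0.67, with -2.53 against WT1 alone and -6.60 against WT2 alone) and NKX6-1 (-2.22 ± 0.30) fell.

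In the WFS1 knockout (ENSG00000109501, chromosome 4, 6269849 to 6303265), of an ER membrane protein gene, 2011 genes passed, 1140 higher and 871 lower, and 558 against both wild-type sets; the lowest count with a library left out was 1154. ER chaperone and unfolded protein response genes fell in 9 of 26 (13 adjusted over the list alone; adjusted p = 4.8e-05, and adjusted p = 0.11 with an estimated correlation). HERPUD1 was at 103 ± 16 against 136 ± 8.9 CPM (-0.40 ± 0.09), with adjusted p = 0.053 in a fit of the knockout and wild type alone. Immediate early genes fell in 15 of 25 and rose in 1 (19 and 1 adjusted over the list alone; adjusted p = 1.5e-13, and adjusted p = 0.072 with an estimated correlation). Members included EGR1 (-1.37 ± 0.19), EGR2 (-1.80 ± 0.31) and EGR3 (-2.77 ± 0.46). Liver and intestine endoderm genes fell in 11 of 26 and rose in 1 (13 and 2 adjusted over the list alone; adjusted p = 2.4e-06, and adjusted p = 0.17 with an estimated correlation). Members included ALDOB (-2.78 ± 0.37) and MTTP (-0.87 ± 0.15). The endocrine transcription factor gene PAX4 (1.26 ± 0.19) and PLAU (2.52 ± 0.31) rose, NLRP2 fell (-4.22 ± 0.10), and ZNF93 was at least 390-fold lower. NKX6-1 did not pass (0.51 ± 0.23), with 154 ± 82 CPM.

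In the GCKR knockout (ENSG00000084734, chromosome 2, 27496839 to 27523684), of the glucokinase regulator, 1411 genes passed, 652 higher and 759 lower, and 236 against both wild-type sets. HNF1A-dependent genes fell in 8 of 29 (11 adjusted over the list alone; adjusted p = 8.1e-05, and adjusted p = 0.13 with an estimated correlation). Members included SERPINA1 at 3940 ± 100 against 5420 ± 480 CPM (-0.46 ± 0.10). MGMT (-5.34 ± 0.38), ZNF793 (-3.80 ± 0.31) and RAMP3 (-3.06 ± 0.37) fell, and CXCL8 (2.40 ± 0.41), the calretinin gene CALB2 (1.99 ± 0.30) and UGT3A1 (1.73 ± 0.19) rose. The count was between 394 and 2431 with 1 library left out, and SERPINA1 had adjusted p = 0.052 without GCKR replicate 2.

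In the knockout of SLC30A8 (ENSG00000164756, chromosome 8, 116950273 to 117176714), which encodes the zinc transporter of insulin granules, 165 genes passed, 64 higher and 101 lower, and 58 against both wild-type sets. Cell cycle genes fell in 3 of 28 (9 adjusted over the list alone; adjusted p = 2.5e-08, and adjusted p = 0.17 with an estimated correlation). Members included MKI67 at 3.04 ± 0.30 against 7.08 ± 1.1 CPM (-1.20 ± 0.28, adjusted p = 0.019, and between 0.10 and 0.16 without any 1 of the knockout's libraries). Acinar cell genes rose in 3 of 12 (3 adjusted over the list alone; adjusted p = 0.0011, but 0.24 against WT2 alone, and adjusted p = 0.090 with an estimated correlation). Members included the trypsinogen gene PRSS2 (1.59 ± 0.29). SERPINE1 rose (1.67 ± 0.24) and CD177 fell (-2.19 ± 0.35). NKX6-1 (-0.86 ± 0.27), PDX1 (-0.51 ± 0.18), INS (-0.28 ± 0.27), GCG (0.22 ± 0.21) and SST (-0.25 ± 0.18) did not pass. With 1 library left out the count ran from 17 to 414.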

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

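Groups of 4 or 6 libraries were tested for a library far from the others with Dixon's ratio. These were the library totals of wild type and of the WFS1 knockout, the 20 targeted genes and 6 endocrine genes in wild type, and the genes named in the WFS1 knockout, 44 groups in all. Chance would flag about 2.2 of the 44, and 2 were flagged. For NKX6-1 in wild type the ratio was 0.71, with WT2 replicate 2 at 80 CPM where the median of the others was 116. For MAFA in wild type it was 0.66, with WT2 replicate 3 at 0.843 CPM where the median of the others was 0.132. NKX6-1 was lower in the same 17 knockouts against WT1 alone and against WT2 alone. No explanation was tested.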

How the results depend on the processing

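The GC and length correction, the count against both wild-type sets and the comparison of group means were chosen after seeing the data. Counts of genes past the threshold, list calls, named genes and r were recomputed under each alternative. They stayed within 1.5 times the reported count, or for r within its jackknife spread, in 27 of 27 results with RLE size factors, 25 of 26 with DESeq2, 26 of 27 with the replicate number as a block and 23 of 27 without a filter. They did so in 20 of 24 against WT1 alone, 17 of 24 against WT2 alone, 20 of 27 with the trends on GC content and length removed and 12 of 27 in a fit of only the groups compared. Where no cause is named below, the cause was not tested.

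A fit of only the groups compared, which has fewer libraries and its own filter on low counts, called 4166 genes in ABCC8, 2036 in APOE, 2121 in CDC123, 3920 in CDKAL1, 482 in GCKR, 5949 in HNF1A, 2466 in HTT, 701 in IGF2BP2, 4314 in KCNJ11, 28 in SLC30A8, 4739 in TCF7L2, 663 in TLE4, 763 in TMCC2 and 448 in WFS1. WT1 alone called 584 in GCKR, 4695 in IGF2BP2, 321 in SLC30A8 and 4636 in TMCC2. WT2 alone called 5576 in APOE, 5907 in GCKR, 3614 in SLC30A8, 4619 in TLE4 and 3612 in WFS1. Without a filter, GCKR had 2159 and SLC30A8 690, and DESeq2 called 310 in SLC30A8. With the trends removed, APOE had 5544, GCKR 2145, SLC30A8 463, TLE4 4133, TMCC2 4654 and WFS1 3150. Besides KCNJ11, GIPR and ABCC8, log2 fold changes correlated with GC share in other knockouts. There r was -0.57 in GCKR, -0.45 in SLC30A8, 0.44 in HNF1A, 0.43 in CDKAL1 and 0.4 in IGF2BP2.

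By construction fewer genes passed against WT1 and against WT2 than against all 6 libraries: 3139 in ABCC8, 1531 in APOE, 1962 in CDC123, 3555 in CDKAL1, 1902 in COBLL1, 236 in GCKR, 4022 in GIPR, 5499 in HNF1A, 6259 in HNF4A, 2069 in HTT, 875 in IGF2BP2, 4327 in KCNJ11, 58 in SLC30A8, 2801 in SLC16A11, 3903 in TCF7L2, 2222 in TGFB1, 906 in TLE4, 1163 in TMCC2, 2119 in WDR13 and 558 in WFS1. The comparison of group means with limma, with 1 value per group, called 1205 in HNF4A, 1525 in KCNJ11, 250 in HNF1A, 100 in CDKAL1, 34 in WDR13 and 30 in TCF7L2. With the trends removed it called 2263 in HNF4A, 1 in KCNJ11 and 201 in HNF1A. Without that correction it called 2 in IGF2BP2 (IGF2BP2 and AP004290.1), 2 in TGFB1 (TGFB1 and ZNF879) and 2 in TLE4 (DUXAP10 and AP000525.1). It called 1 in APOE (APOE), 1 in GIPR (GLUD2), 1 in SLC30A8 (RWDD2B), 1 in SLC16A11 (TAFA3), 1 in TMCC2 (KLHL34) and 1 in WFS1 (AC138356.2), genes named after their values were seen. It called 0 in ABCC8, CDC123, COBLL1, GCKR and HTT, where 241, 491, 548, 257 and 567 genes had an unadjusted p under 0.05. Each is below 0.05 of the genes tested, but the effects of the other knockouts add to the spread in this test. A low count there does not show that a knockout had no effect.

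With 1 library left out the lowest and highest counts were 3805 (without ABCC8 replicate 2) and 7199 in ABCC8, 2290 (without APOE replicate 3) and 3770 in APOE, 2841 (without CDC123 replicate 1) and 4854 in CDC123. They were 2815 (without COBLL1 replicate 1) and 4756 in COBLL1, 394 (without GCKR replicate 2) and 2431 (without WT1 replicate 3) in GCKR, 6384 (without HNF1A replicate 4) and 9792 in HNF1A. They were 1235 (without IGF2BP2 replicate 2) and 2983 in IGF2BP2, 5731 (without KCNJ11 replicate 3) and 9195 in KCNJ11, 17 (without SLC30A8 replicate 2) and 414 (without WT1 replicate 1) in SLC30A8, 3312 (without TGFB1 replicate 1) and 5396 in TGFB1. They were 1611 (without TLE4 replicate 1) and 2912 in TLE4, 1821 (without TMCC2 replicate 1) and 2982 in TMCC2, 1154 (without WFS1 replicate 3) and 2342 in WFS1. They were 3143 (without WT1 replicate 3) and 4256 between WT1 and WT2, and 3581 (without HNF1A replicate 4) and 6158 between HNF1A and HNF4A. The other 8 comparisons stayed within 1.5 times.

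The list calls numbered 39 with an estimated correlation, all among the 211 reported, and between 185 and 282 under the other alternatives; WT1 alone kept 163 of the 211, WT2 alone 145 and the correction 181, with 0 turned. For ABCC8 and KCNJ11 r was -0.21 and -0.09 with split controls, 0.3 without a filter, 0.38 against WT2 alone and 0.24 with the trends removed. For HNF1A and HNF4A it was 0.45 and 0.52 with split controls, 0.53 without a filter, 0.74 against WT2 alone, 0.73 in a fit of only the groups compared and 0.62 with the block.

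Among the named genes, 5 that passed the threshold in the reported fit or under the alternative changed sign between them. Named values that passed in neither also changed sign, such as INS in HNF1A, 0.45 against WT1 alone. PDX1 in KCNJ11 was 0.04 against WT1 alone and 0.12 with the trends removed. SLC30A8 in its own knockout was 0.67 against WT2 alone. With the trends removed INS and SST in GIPR were -0.06 and -0.04, and SLC16A11 in its own knockout was -0.4. Among the named values PDX1 also lost its call against WT1 alone in ABCC8, GIPR, IGF2BP2 and TGFB1, and INS lost it against WT2 alone in GIPR, SLC16A11 and TGFB1.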

Other observations

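The tests of GC content and length, of depth and of shared states were chosen after the results were seen, while the other splits of the samples, the library left out and the thinning to equal totals were planned before.

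Some genes moved the same way in nearly every knockout. CD8B and LMO4 were higher in 19 of the 20, with median levels over the knockouts of 8.1 and 19.6 CPM, against 2.23 and 11.9 in WT1 and 1.38 and 8.07 in WT2. HPGD, SLC4A11 and TMEM132D were higher in 18. MAGEA4 and ZNF662 were lower in 19, and ZFP3, EOLA1 and KCNMA1 were among the 8 lower in at least 18. These genes were picked for their recurrence after their values were seen. Genes named above under single knockouts recurred as well. NKX6-1, DCLK1, ACP5 and DRAIC passed in the same direction in 17, and TPH1, MIAT, TP63 and TF in 16. As the knockouts share the same 6 controls, a recurrent change can lie in the wild-type libraries as much as in the knockouts, and the design does not separate these.

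Other genes were near 0 in every library of some groups and clearly expressed in the rest. Of 12238 genes with a median group level of at least 5 CPM, 117 were at least 16-fold under it in every library of 1 or more groups, and 34 in 2 or more, where 1000 random draws gave a mean of 0.6 and at most 4. In both the HNF1A and HNF4A knockouts 27 of the 34 were near 0, among them SERPINA1, AFP, GC and DPP4. The others were near 0 in other sets of knockouts, such as ZNF107 in 8, ZNF93 in 4 and CHCHD2 in 3, and none was near 0 in WT1 or WT2. Low depth is argued against by the lowest count that the median level would give over such a group, 384, and bias from GC content or length by the 76 of 77 gene and group pairs that stayed near 0 with the trends removed. ZNF107 and ZNF793 were both under 1 CPM in the same 9 of 22 groups (Fisher's exact p = 2e-06, two-sided), but both were picked for this pattern, so the p decides nothing. Whether a silenced state was handed down among related lines stays open. All cells came from MEL1, but the sources used here do not give which lines share a parent clone.

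The KCNJ11 knockout had 8598 genes past the threshold and libraries with a steep trend on GC content. With the trends on GC content and length removed 6494 passed, and without KCNJ11 replicate 3 there were 5731, so neither the trends nor that library alone account for the whole count. Against the other 21 group means the count went from 1525 to 1 with the trends removed, so for that comparison a bias from GC content and length is a likely cause. What gave these libraries their trend, and how much of the rest follows from the loss of KCNJ11, was not tested.

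WT1 and WT2 share a genotype, yet 5002 genes differed between them. Their log2 fold changes correlated with GC share (r = -0.56). With the trends on GC content and length removed 5146 differed, of which 3438 had also differed before, in the same direction. In a fit of the 6 libraries alone 6102 differed, against 5712 after thinning each to the smallest total of 12157013 counts, so neither the trends nor library size account for the whole count. What WT1 and WT2 stand for is not given in the sources used here, and a difference between clones or between differentiations remains open and untested.

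For each comparison the libraries were also split in every other way into groups of the same sizes, in fits of only those libraries. The count of the real split was the highest of 84 splits, 1 of 84, for 9 knockouts. These were ABCC8 (4166, highest other 3186), CDC123 (2121 and 1944), CDKAL1 (3920 and 3292), GIPR (5924 and 4549), HNF1A (5949 and 2237), HNF4A (8402 and 2774), KCNJ11 (4314 and 3557), SLC16A11 (4112 and 3398) and TCF7L2 (4739 and 3659). In 2 of 84 splits, the real one included, as many genes passed for APOE (2036, highest other 4273), COBLL1 (3487 and 4226), GCKR (482 and 7441), HTT (2466 and 3227), TGFB1 (3612 and 4662) and WDR13 (3291 and 4198). In 3 of 84 they did for IGF2BP2 (701 and 3743), SLC30A8 (28 and 5792), TLE4 (663 and 2952) and TMCC2 (763 and 3357), and for WFS1 in 3 of 100 drawn from 210 (448 and 1704). The share was under 0.05 for all 20. However, the median count of the other splits was 0 in each, as nearly all of them mix libraries of different groups, so a low share is what any group of like libraries would give and it does not show an effect of the knocked-out gene. The highest other split set WT1 or WT2 apart in each, joined by WFS1 replicate 4 in 1 of them, and for GCKR, IGF2BP2, SLC30A8, TLE4, TMCC2 and WFS1 it called several times the real count. That points to a structure of the samples, the difference between WT1 and WT2, of the same order as many of the knockouts. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real and highest other counts there were 6102 and 0 between WT1 and WT2, 9432 and 0 between ABCC8 and KCNJ11, and 4618 and 0 between HNF1A and HNF4A.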
